A study of Homo sapiens with 36 samples.

How the data were processed

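UM-SCC-1, an established line from a head and neck squamous cell carcinoma, was transduced with retroviruses carrying a scramble shRNA or 1 of 2 shRNAs against ALKBH5 or RBM33. Per the labels' protocols, cells were selected with 10 ug/mL blasticidin for 4 days, RNA was fragmented by sonication, and libraries were made with a stranded total RNA kit and sequenced on a NovaSeq instrument. The design text speaks of siRNA while the sample titles name shRNA, and the titles are followed here. The labels list 36 samples in 12 groups of 3, of which 18 are RNA-seq inputs and 18 are m6A-seq libraries, in which RNA carrying N6-methyladenosine was enriched. The ALKBH5 set and the RBM33 set each have their own scramble group. The labels do not say that replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical.

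The per-library table was deposited as signal in the sense used here: CPM (read counts scaled to a common total) of a normalized library size, as made by the authors. Its columns sum to slightly different totals, which is why the unit is treated as a normalized signal and the test was chosen for such values. It gives 15 of the 18 RNA-seq libraries, so the ALKBH5 shRNA-1, ALKBH5 shRNA-2 and RBM33 shRNA-1 groups enter with 2 libraries and the other groups with 3. The remaining 3 libraries were not analysed here. The number of columns from other samples was 0. Per the submitters' processing notes, reads were trimmed with cutadapt 1.18, aligned with HISAT2 2.1.0 to hg38, counted with featureCounts (Subread 1.6.4) and compared with edgeR 3.24.3, and DESeq2 is named without a version. The authors deposited log2 fold changes and adjusted p-values of each shRNA against its scramble in tables from edgeR and from DESeq2, and the DESeq2 tables also give a mean normalized signal per gene. For one DESeq2 table (RBM33 shRNA-1) the fold changes have the form of shrunken values.

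For m6A, the authors deposited 4 tables of differential peaks with an effect and a p-value per peak, and 4 tables in which the m6A level of a peak is given as a fraction with an adjusted p-value. The peak caller is not given in the sources used here. The deposited effects are on the natural log scale: between 5.6% and 7.86% of them are logarithms of multiples of 0.5 within 1e-06, against 0% on a log2 scale. The lowest absolute effect in each table is 0.5, so smaller effects are outside these tables. No m6A value per library was used, so the spread between m6A replicates could not be computed, and effects and p-values are the authors'. Coordinates are those of the deposited tables (hg38), written from base 1. Gene spans come from the deposited gene table and from a RefSeq gene table, which gives no exons or untranslated regions, so the part of a transcript in which a peak lies is not analysed here. Between 93.5% and 93.9% of the genes of an effect table matched a tested gene by symbol. Histone genes carry older symbols there that did not all match, so the m6A of the histone list is not analysed here.

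Whole reads were recovered from the CPM: in each library, 100% of the values were whole multiples of 1 read within 0.1 of a read. Libraries held between 4493849 and 6733017 reads in the 21797 listed genes, and 1 read was worth between 0.14335 and 0.21983 CPM. A count of 0 in a library allows a level of up to 3 reads, or between 0.43 and 0.6595 CPM. Intervals and floors of this kind cover counting error only. Replicate pairs within a group differed by more than sampling noise, with a chi-square per degree of freedom between 2.9 and 8.04. No pair was therefore merged as 1 library sequenced again, and every library was counted as a sample of its own. Such a spread does not show that the libraries come from separate cultures.

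The main test was limma (3.58.1, R 4.3.3) with a mean-variance trend on log2(CPM + 1) over the 18227 genes with a mean of at least 1 CPM, in one fit of 6 group means with 9 residual degrees of freedom. With all 18 libraries the fit would have had 12. Fold changes on the log2(CPM + 1) scale understate the change of genes with low values. Benjamini-Hochberg adjusted p-values under 0.05 were called changed. Contrasts compared each shRNA with its scramble, the mean of both shRNAs with the scramble, the ALKBH5 effect with the RBM33 effect (an interaction), the shRNAs of 1 target with each other and the scramble groups with each other. The groups, these tests, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The ALKBH5 shRNA libraries were also compared directly with the RBM33 shRNA libraries, a comparison chosen after seeing the data.

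A total of 26 gene lists were tested with camera, at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over all 260 tests of 26 lists in 10 contrasts. The lists cover m6A machinery, autophagy and lysosome, mTORC1 regulators, the ATF4 stress response, hypoxia and glycolysis, p53 targets, cell cycle, interferon response, NF-kB inflammatory genes, keratinocyte differentiation, basal squamous progenitors, mesenchymal genes, YAP targets, cholesterol synthesis, ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes, SR and hnRNP splicing factors, mRNA export, nuclear noncoding RNA, replication histones, and markers of fibroblasts, leukocytes, endothelium, neural or melanocyte cells and epithelium. The fry test was run beside camera. It asks whether the genes of a list move on balance one way and does not compare the list with other genes.

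Named genes followed a rule. It takes ALKBH5, RBM33 and DDIT4, the last from knowledge of a later publication of the study. It takes, for each target, the 12 protein-coding genes with the largest rise and the 12 with the largest fall. These had to pass in both shRNAs, have a mean of at least 5 CPM in the set's libraries (7 for ALKBH5 and 8 for RBM33) and show no overlap between scramble and shRNA libraries. By these criteria 517 genes rose and 376 fell in the ALKBH5 set, and 626 rose and 551 fell in the RBM33 set. The rule adds the 6 rises and 6 falls with the largest change shared by both sets, up to 4 passing members of each list, and from each m6A table the 5 genes with the most significant peaks, the 3 with the largest effects and up to 10 genes higher in both sets. Some genes that meet the rule are not reported. The heat shock genes other than HSPA1A, HSPA1B and HSPA6, the m6A peaks of AMH, HSPA1A and ATF4, and the levels of IGF2BP1, NEFM and LIN28B were chosen after their values were seen.

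Comparisons sharing a scramble group were set beside 20 simulated runs with unchanged groups. The RNA change of genes with differential m6A was compared with 10000 random gene sets of the same size matched on mean expression in 20 bins. The overlap of m6A genes was tested with Fisher's exact test (two-sided) and with a Mantel-Haenszel odds ratio within 10 expression deciles. Alternatives were a pseudocount of 0.25, no filter, a mean of at least 5 CPM, TMM rescaling, a replicate block, fits to the libraries of 1 set, each library left out, edgeR (4.0.16) quasi-likelihood and DESeq2 (1.42.0) on the recovered reads, stricter m6A peaks (p under 0.01 and an absolute effect of at least 1), and an overlap of at least 50% of both peaks. Removal of a gene length trend from each library, the direct comparison of the shRNA libraries and the left-out libraries for the gene lists were added after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

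The fit was tested on simulated data with known changes in 18184 genes. For both ALKBH5 shRNAs against scramble it recovered 45.5% of genes changed 1.5-fold, 76.2% of those changed 2-fold and 95.2% of those changed 4-fold. Of its 150 calls there, 12 were unchanged genes. For both RBM33 shRNAs the shares were 40.9%, 79.4% and 95.2%, and 7 of 144 calls were unchanged genes. Unchanged genes made up 13 of 135 calls for ALKBH5 shRNA-1 and 8 of 139 for RBM33 shRNA-2. With no simulated change, the interaction called 3 genes and the scramble comparison 0. A simulated list of 30 genes shifted by 0.5 had a camera adjusted p of 2.1e-33, and 0 of the other simulated lists passed. The simulated genes varied independently of each other, so false calls for lists of correlated genes were not tested.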

Results

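The series asks how the RNA and the m6A methylation of UM-SCC-1 cells differ when ALKBH5 or RBM33 is targeted by shRNA. ALKBH5 is a demethylase that removes N6-methyladenosine (m6A) from RNA, and RBM33 is an RNA-binding protein known to interact with it. RNA-seq values were analysed for 15 libraries: 3 ALKBH5 scramble, 2 ALKBH5 shRNA-1, 2 ALKBH5 shRNA-2, 3 RBM33 scramble, 2 RBM33 shRNA-1 and 3 RBM33 shRNA-2. Depth in listed genes ranged from 4493849 reads (RBM33 shRNA-2 replicate 1) to 6733017 reads (ALKBH5 shRNA-1 replicate 1). For m6A, only the authors' deposited comparisons were used.

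The ALKBH5 transcript (ENSG00000091542, chromosome 17, 18183078 to 18209954) was at 108.8, 131.7 and 123.3 CPM in the ALKBH5 scramble libraries. It was at 84.72 and 84.77 CPM with shRNA-1 and at 75.08 and 89.59 CPM with shRNA-2. Over both shRNAs ALKBH5 fell by 0.53 on the log2 scale (SE 0.08, limma adjusted p = 9.1e-05), leaving 69.2% of the scramble level. The RBM33 transcript (chromosome 7, 155644451 to 155781485) was at 217.1, 207.2 and 227.1 CPM in the RBM33 scramble libraries. In the libraries labelled RBM33 shRNA it was at 191.4 and 204 CPM (shRNA-1) and at 207.7, 199.3 and 214.4 CPM (shRNA-2). Its difference over both shRNAs was -0.10 (SE 0.06, 95% interval -0.23 to 0.02, limma adjusted p = 0.27), so RBM33 was not called reduced, and only with a gene length trend removed did it pass, at -0.20 (limma adjusted p = 0.027). In the authors' deposited edgeR tables the RBM33 change was -0.13 (FDR 0.33) and -0.07 (FDR 0.62). These libraries are therefore named by their label throughout, and directions drawn from them rest on that label. ALKBH5 itself differed by -0.06 in the libraries labelled RBM33 shRNA (limma adjusted p = 0.63).

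DDIT4 (chromosome 10, 72273924 to 72276036), which encodes an inhibitor of mTORC1 signalling, fell in both sets. It was at 293.7, 293.7 and 313.5 CPM in the ALKBH5 scramble libraries and between 157 and 174.3 CPM in the ALKBH5 shRNA libraries, a log2 change of -0.84 (SE 0.07, limma adjusted p = 1.4e-08). In the RBM33 set it was at 361.4, 368.6 and 320.9 CPM with scramble and between 161.7 and 181.8 CPM in the libraries labelled RBM33 shRNA, a log2 change of -1.04 (SE 0.07, limma adjusted p = 7.8e-11). The difference between both changes was 0.20 (SE 0.10, limma adjusted p = 0.32).

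**Figure D1:**
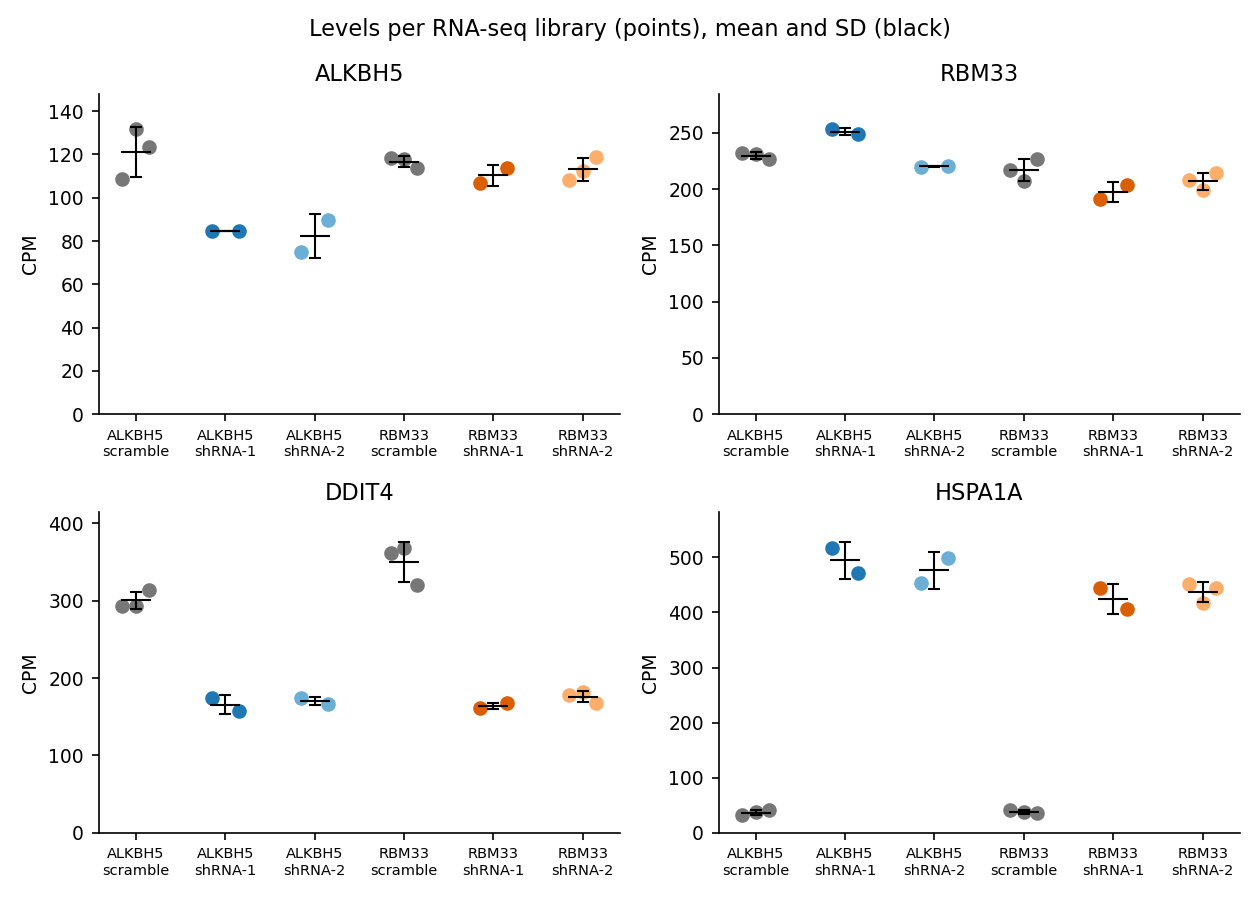
CPM of ALKBH5, RBM33, DDIT4 and HSPA1A (y axes, from 0) in each of the 15 RNA-seq libraries (points) by group, with the group mean and SD in black. ALKBH5 was lower in its shRNA libraries, RBM33 differed little between the libraries of its set, DDIT4 fell in both sets and HSPA1A rose from between 31.53 and 41.38 CPM in scramble libraries to between 405.4 and 517.6 CPM in shRNA libraries.

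In the ALKBH5 shRNA libraries the largest rise was in ANKRD1, which encodes a cardiac ankyrin repeat protein and is a known YAP target, with a log2 change of 4.79 (SE 0.21, limma adjusted p = 5.3e-14). The inducible HSP70 genes HSPA1B (3.84, SE 0.09), HSPA1A (3.70, SE 0.08) and HSPA6 (3.46, SE 0.29) rose with it. HSPA1A and HSPA1B are near-identical copies, so their separate values are uncertain. AMH rose by 3.26 (SE 0.15) and lies next to SF3A2, so reads running through from its neighbour cannot be told from its own. The immediate early genes FOSB (2.57, SE 0.21) and FOS (2.1, SE 0.30) also rose, as did the dynein heavy chain genes DNAH17 (2.49, SE 0.13) and DNAH1 (1.85, SE 0.18), MYH3 (1.58, SE 0.20), COL7A1, which encodes anchoring fibril collagen (1.47, SE 0.26), and NEB (1.37, SE 0.17). Limma adjusted p of these genes ranged up to 0.0005.

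The largest falls in the ALKBH5 shRNA libraries included G0S2, an inhibitor of lipolysis (log2 change -2.08, SE 0.23, limma adjusted p = 1.3e-06), and TXNIP, a thioredoxin-binding regulator of glucose uptake (-1.34, SE 0.09, limma adjusted p = 1.7e-10). The sodium channel gene SCN9A (-1.30, SE 0.27), PPDPF (-1.16, SE 0.12), the collagen crosslinking enzyme LOX (-1.10, SE 0.14), RIMS3 (-1.09, SE 0.22) and the epoxide hydrolase EPHX2 (-1.08, SE 0.15) fell as well. So did INHBE (-1.06, SE 0.18), CREG2 (-1.06, SE 0.22) and GCNT1 (-1.05, SE 0.21). HSPA5, which encodes the endoplasmic reticulum chaperone BiP, fell by 1.05 (SE 0.07, limma adjusted p = 1.7e-10), and SLC37A4 fell by 1.04 (SE 0.11). BASP1 had a log2 change of -1.46 (SE 0.36, limma adjusted p = 0.0073), which did not pass without ALKBH5 scramble replicate 2 (-1.21, limma adjusted p = 0.055).

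Of the ATF4 stress response list, 13 of 28 measured members fell and 4 rose in the ALKBH5 shRNA libraries (17 and 5 adjusted over the list alone). The falls included asparagine synthetase, ASNS (-0.67, SE 0.07), and HERPUD1 (-0.65, SE 0.08), a component of endoplasmic reticulum degradation. The list median was -0.25, with a camera adjusted p of 2.9e-05 and an adjusted p = 0.023 with an estimated correlation. Ribosomal protein genes went up, with 36 of 66 rising and 0 falling (39 and 0 adjusted over the list alone), among them RPL27 (0.71, SE 0.11), RPL35 (0.63, SE 0.10) and RPS27 (0.61, SE 0.10), with a camera adjusted p of 7e-17 and adjusted p = 0.36 with an estimated correlation. Nuclear genes of oxidative phosphorylation rose in 11 of 37 cases and fell in 1 (15 and 2 adjusted over the list alone), led by the cytochrome oxidase subunits COX6A1 (1.07, SE 0.10) and COX6C (0.79, SE 0.11), with a camera adjusted p of 5.8e-07 and adjusted p = 0.23 with an estimated correlation. Mitochondrially encoded genes fell in 8 of 13 cases and rose in 0 (9 and 0 adjusted over the list alone), such as MT-ATP8 (-0.74, SE 0.12), MT-ND4 (-0.67, SE 0.11) and MT-ND5 (-0.64, SE 0.09). Their camera adjusted p was 5.9e-08, and adjusted p = 0.34 with an estimated correlation. Without ALKBH5 scramble replicate 1 the median of the mitochondrially encoded genes moved from -0.35 to -0.18 (camera adjusted p = 4.8e-05).

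SR and hnRNP splicing factor genes rose in 12 of 33 cases and fell in 2 (15 and 3 adjusted over the list alone) in the ALKBH5 shRNA libraries, including SRSF2 (0.56, SE 0.09), HNRNPM (0.48, SE 0.07) and SRSF6 (0.44, SE 0.08), with a camera adjusted p of 0.00056 and adjusted p = 0.23 with an estimated correlation. Genes of mRNA export rose in 9 of 21 cases and fell in 1 (9 and 1 adjusted over the list alone), including the helicase DDX39A (1.10, SE 0.10), ALYREF (0.86, SE 0.09), SRRT (0.79, SE 0.08) and the export receptor NXF1 (0.76, SE 0.11), with a camera adjusted p of 0.0022 and adjusted p = 0.14 with an estimated correlation. Autophagy and lysosome genes had 5 rises and 3 falls among 36 (7 and 3 adjusted over the list alone), with the autophagy receptor SQSTM1 up by 0.91 (SE 0.09) and the receptor OPTN down at -0.61 (SE 0.14). Their camera adjusted p of 0.045 (adjusted p = 0.14 with an estimated correlation) did not pass without ALKBH5 scramble replicate 1 or 2, shRNA-1 replicate 2 or shRNA-2 replicate 3, where the adjusted p reached 0.069. Of 24 p53 targets 6 rose and 1 fell (6 and 1 adjusted over the list alone), including the apoptosis effector BAX (1.32, SE 0.19) and AEN (0.52, SE 0.09). The camera adjusted p of 0.047 for p53 targets (adjusted p = 0.18 with an estimated correlation) did not pass without ALKBH5 scramble replicate 2 or 3, shRNA-1 replicate 1 or shRNA-2 replicate 1 or 3, where it reached 0.097.

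The other lists did not pass in camera in the ALKBH5 shRNA libraries. Hypoxia and glycolysis genes had 3 rises and 10 falls among 28 (5 and 11 adjusted over the list alone, camera adjusted p = 0.21), and the glycolytic enzyme PGK1 rose by 0.86 (SE 0.06). mTORC1 regulators had 8 rises and 3 falls among 34 (8 and 5 adjusted over the list alone, camera adjusted p = 0.40), including RPTOR, the scaffold of the complex (0.57, SE 0.09), and FNIP1 (0.56, SE 0.11). Cell cycle genes had 7 rises and 8 falls among 38 (10 and 11 adjusted over the list alone, camera adjusted p = 0.54), with CCNE2 up (0.61, SE 0.15) and topoisomerase TOP2A down (-0.53, SE 0.07). The m6A machinery had 3 rises and 1 fall among 27 (4 and 1 adjusted over the list alone, camera adjusted p = 0.68), with RBMX (0.50, SE 0.06) and the reader YTHDC1 (0.37, SE 0.07) up. Cholesterol synthesis had 2 rises and 4 falls among 23 (2 and 5 adjusted over the list alone, camera adjusted p = 0.24), with INSIG1, a regulator of sterol synthesis, down (-0.54, SE 0.11). Nuclear noncoding RNA had 5 rises and 0 falls among 18 (5 and 0 adjusted over the list alone), with the 7SK RNA, RN7SK, up by 0.97 (SE 0.10). The camera adjusted p of this list was 0.27, and its median of -0.05 has the opposite sign to the test. Replication histones had 3 rises and 2 falls among 13 (4 and 2 adjusted over the list alone, camera adjusted p = 0.71), with a median of -0.02 against an upward test.

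Counts in the remaining lists were small in the ALKBH5 shRNA libraries. Interferon response genes had 0 rises and 2 falls among 17 (0 and 1 adjusted over the list alone, camera adjusted p = 0.49), and NF-kB genes had 1 rise and 0 falls among 7 (1 and 0 adjusted over the list alone, camera adjusted p = 0.18). Keratinocyte differentiation genes had 0 rises and 2 falls among 7 (0 and 2 adjusted over the list alone, camera adjusted p = 0.49), 1 of them the keratin KRT10 (-0.60, SE 0.11). Basal squamous genes had 1 rise and 0 falls among 19 (1 and 0 adjusted over the list alone, camera adjusted p = 0.99, median -0.07 and mean 0.09), and mesenchymal genes had 1 rise and 1 fall among 17 (1 and 2 adjusted over the list alone, camera adjusted p = 0.92), namely vimentin, VIM (0.32, SE 0.06), and fibronectin, FN1 (-0.68, SE 0.10). YAP targets had 2 rises and 2 falls among 20 (4 and 4 adjusted over the list alone, camera adjusted p = 0.76), with a median of -0.07 and a mean of 0.24. Among markers of other cell types, where adjustment over the list alone added only 1 endothelial fall, fibroblast genes had 1 fall among 11 (COL6A1, -0.59, SE 0.13, list camera adjusted p = 0.49), leukocyte genes had 0 changes among 5 (0.77, median 0.07 against a downward test), endothelial genes had 1 fall among 3 (EGFL7, -0.76, SE 0.13, list 0.21), neural or melanocyte genes had 1 rise among 8 (0.73), and epithelial genes had 1 rise and 1 fall among 7 (KRT8, 0.50, SE 0.11, and OCLN, -0.53, SE 0.11, list 0.61).

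In all, limma called 2754 of 18227 genes changed over both ALKBH5 shRNAs, 1446 higher and 1308 lower, and 206 of them differed at least 2-fold (160 higher, 46 lower). Without ALKBH5 scramble replicate 1 the count was 1710. Taken singly, shRNA-1 gave 1555 genes (921 higher, 634 lower) and shRNA-2 gave 1834 (922 higher, 912 lower). The shRNA-1 count was 928 without scramble replicate 1, and 541 and 751 without shRNA-1 replicates 1 and 2. The shRNA-2 count was 1164 without scramble replicate 1, and 592 and 1178 without shRNA-2 replicates 1 and 3. Both shRNAs shared 1009 genes changed the same way and 0 changed the opposite way, against 46.6 higher and 31.7 lower for independent lists. Simulations with no effect gave 0.1. They held no changed genes and so could give hardly any calls, which makes this value no measure of agreement. Their log2 changes correlated across genes at 0.69 (genes are not independent replicates) with a covariance of 0.106, against 0.40 and 0.0267 in the simulations, a covariance difference of 0.0796. Part of the excess may come from the shared scramble libraries, which are too few to split.

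The libraries labelled RBM33 shRNA showed many of the same leading genes. ANKRD1 rose by 4.72 (SE 0.20, limma adjusted p = 2.6e-14), followed by AMH (3.57, SE 0.15), HSPA1A (3.47, SE 0.08) and HSPA1B (3.45, SE 0.09), with the same doubts about AMH and the HSP70 copies. DNAH17 (2.43, SE 0.12), FOSB (2.17, SE 0.21), DNAH1 (1.89, SE 0.17), NEB (1.88, SE 0.16), MYH3 (1.76, SE 0.19), CCDC168 (1.76, SE 0.24), FOS (1.75, SE 0.29), the methyl-CpG-binding domain gene MBD6 (1.74, SE 0.15) and COL7A1 (1.32, SE 0.25) rose as well. The largest falls were in G0S2 (-2.82, SE 0.22, limma adjusted p = 4.6e-09) and BASP1, which encodes a membrane-bound growth cone protein (-2.06, SE 0.35). PRADC1 (-1.42, SE 0.29), TXNIP (-1.41, SE 0.08), BTBD2 (-1.31, SE 0.11), SCRN2 (-1.30, SE 0.20), HSD17B8 (-1.28, SE 0.29), INHBE (-1.28, SE 0.17), MFSD3 (-1.19, SE 0.23), the creatine synthesis enzyme GAMT (-1.15, SE 0.17), ICAM5 (-1.15, SE 0.18), SLC37A4 (-1.11, SE 0.10), HSPA5 (-1.06, SE 0.07) and LOX (-0.92, SE 0.13) also fell. Limma adjusted p of these genes ranged up to 0.0031.

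Of the ATF4 stress response list, 15 of 28 members fell and 1 rose in the libraries labelled RBM33 shRNA (16 and 1 adjusted over the list alone), including CHAC1 (-1.0, SE 0.16), which degrades glutathione, HERPUD1 (-0.94, SE 0.07) and ASNS (-0.88, SE 0.07). The camera adjusted p was 3.9e-09, and adjusted p = 0.0055 with an estimated correlation. Replication histones fell in 11 of 13 cases (11 adjusted over the list alone), such as H4C3 (-0.96, SE 0.09), H3C2 (-0.87, SE 0.08) and H2AC13 (-0.84, SE 0.09), with a camera adjusted p of 1.3e-13 and adjusted p = 0.049 with an estimated correlation. SR and hnRNP splicing factors rose in 17 of 33 cases and fell in 1 (22 and 2 adjusted over the list alone), including HNRNPM (0.73, SE 0.06), SRSF6 (0.61, SE 0.08) and SON (0.48, SE 0.06), with a camera adjusted p of 7.6e-09 and adjusted p = 0.062 with an estimated correlation. Ribosomal protein genes fell in 21 of 66 cases and rose in 1 (32 and 2 adjusted over the list alone), among them RPL32 (-0.51, SE 0.07), RPS21 (-0.50, SE 0.10) and RPL10 (-0.43, SE 0.07), with a camera adjusted p of 3.6e-08 and adjusted p = 0.54 with an estimated correlation. For histones and ribosomal proteins these changes, and the ribosomal rise in the ALKBH5 set, are measured against scramble groups that differed from each other, by a median of -0.57 for histones and -0.40 for ribosomal proteins (ALKBH5 set minus RBM33 set) while the shRNA libraries differed by 0.12 and 0.01.

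Of 24 p53 targets, 7 rose and 2 fell in the libraries labelled RBM33 shRNA (10 and 2 adjusted over the list alone), including BAX (0.78, SE 0.18), ZMAT3 (0.72, SE 0.14) and MDM2, the p53 ubiquitin ligase (0.52, SE 0.06). Their camera adjusted p was 0.0048, and adjusted p = 0.07 with an estimated correlation. Hypoxia and glycolysis genes fell in 11 of 28 cases and rose in 1 (11 and 1 adjusted over the list alone), with NDRG1 at -0.84 (SE 0.13) and PGK1 at 0.28 (SE 0.06), a camera adjusted p of 0.0032 and adjusted p = 0.24 with an estimated correlation. Cholesterol synthesis genes fell in 7 of 23 cases and rose in 1 (9 and 1 adjusted over the list alone), with MVD (-0.71, SE 0.17), STARD4 (-0.66, SE 0.16) and FDFT1, squalene synthase (-0.49, SE 0.09), down. Their camera adjusted p was 0.0069, and adjusted p = 0.072 with an estimated correlation. Nuclear noncoding RNA fell in 8 of 18 cases and rose in 2 (10 and 2 adjusted over the list alone), with SNHG1 (-0.78, SE 0.13) and the telomerase RNA TERC (-0.69, SE 0.09) down, a camera adjusted p of 0.0044 and adjusted p = 0.44 with an estimated correlation. The scramble groups also differed for noncoding RNA, by a median of -0.43 against 0.04 between the shRNA libraries. Oxidative phosphorylation genes fell in 8 of 37 cases and rose in 2 (10 and 2 adjusted over the list alone), such as COX5A (-0.50, SE 0.10) and UQCRC1 (-0.48, SE 0.09). Their camera adjusted p of 0.047 (adjusted p = 0.60 with an estimated correlation) did not pass without RBM33 scramble replicate 1 or 3, shRNA-1 replicate 1 or shRNA-2 replicate 2, where it reached 0.12, or with the length trend removed (median -0.06, camera adjusted p = 0.089). Without RBM33 shRNA-1 replicate 2 the median of this list moved from -0.08 to -0.13. The scramble groups differed for oxidative phosphorylation as well, by a median of -0.26 against 0.03 between the shRNA libraries. This also concerns the rise of the list in the ALKBH5 set.

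Lists that did not pass in camera in the libraries labelled RBM33 shRNA still held single changes. The m6A machinery had 6 rises and 3 falls among 27 (7 and 3 adjusted over the list alone, camera adjusted p = 0.21), with YTHDC1 (0.59, SE 0.06), RBMX (0.56, SE 0.06) and ZC3H13, a subunit of the writer complex (0.49, SE 0.07), up. Genes of mRNA export had 5 rises and 0 falls among 21 (6 and 1 adjusted over the list alone, camera adjusted p = 0.051), with DDX39A (1.08, SE 0.09) and SRRT (1.05, SE 0.08) up. Autophagy and lysosome genes had 5 rises and 3 falls among 36 (7 and 4 adjusted over the list alone, camera adjusted p = 0.40), including the kinases ULK1 (0.55, SE 0.14) and PIK3C3 (0.53, SE 0.11). mTORC1 regulators had 4 rises and 8 falls among 34 (4 and 8 adjusted over the list alone, camera adjusted p = 0.87), with RPTOR (0.77, SE 0.09), DEPDC5 (0.73, SE 0.16) and FNIP1 (0.65, SE 0.10) up, and the falls including DDIT4. Cell cycle genes had 2 rises and 7 falls among 38 (4 and 13 adjusted over the list alone, camera adjusted p = 0.21), with AURKB (-0.51, SE 0.08) and CDC6 (-0.39, SE 0.07) down and CCND1 (0.35, SE 0.08) up.

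Smaller counts stood in the other lists of the libraries labelled RBM33 shRNA. Interferon genes had 2 falls among 17 (camera adjusted p = 0.60), 1 of them HERC5 (-0.63, SE 0.14). NF-kB genes had 1 fall among 7 (0 rises, but 2 rises adjusted over the list alone, camera adjusted p = 0.38). Keratinocyte differentiation genes had 2 falls among 7 (camera adjusted p = 0.53), basal squamous genes 2 rises and 1 fall among 19 (0.98), mesenchymal genes 2 rises and 3 falls among 17 (0.98), including FN1 (-0.67, SE 0.10), and YAP targets 3 rises and 1 fall among 20 (0.56). Mitochondrially encoded genes had 1 rise among 13 (0 adjusted over the list alone), with a camera adjusted p of 0.99 and a median of -0.02 against an upward test. Among markers of other cell types, fibroblast genes had 4 falls among 11 (camera adjusted p = 0.079), including COL6A1 (-0.62, SE 0.12), leukocyte genes 1 fall among 5 (0.37), endothelial genes 1 fall among 3 (EGFL7, -1.0, SE 0.13, list 0.20), neural or melanocyte genes 0 changes among 8 (0.70) and epithelial genes 1 fall among 7 (2 adjusted over the list alone, 0.22).

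Limma called 3235 genes changed over both shRNAs labelled RBM33, 1549 higher and 1686 lower, and 279 differed at least 2-fold (158 higher, 121 lower). The count was 2083 without RBM33 scramble replicate 1 and 2062 without replicate 2. Taken singly, shRNA-1 gave 1985 genes (1024 higher, 961 lower) and shRNA-2 gave 2499 (1174 higher, 1325 lower). The shRNA-1 count was 1286 and 1275 without scramble replicates 1 and 2, and 953 and 1018 without shRNA-1 replicates 1 and 2. Both shRNAs shared 1402 genes changed the same way and 0 the opposite way, against 66 higher and 69.9 lower for independent lists. The value of 0.2 in simulations with no effect is again no measure of agreement. Their log2 changes correlated across genes at 0.76 with a covariance of 0.124, against 0.45 and 0.0266 in simulations, a covariance difference of 0.097. Here too the scramble libraries are shared, and part of the excess may come from them.

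Direct comparison of the shRNAs against 1 target called 0 genes in limma for ALKBH5 shRNA-2 against shRNA-1, with 943 genes at an unadjusted p under 0.05, 0 genes by edgeR and 1 by DESeq2. For the libraries labelled RBM33 shRNA-2 against shRNA-1 it also called 0, with 994 genes at an unadjusted p under 0.05 and 0 by both edgeR and DESeq2.

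Genes changed the same way in both sets numbered 1120, 583 higher and 537 lower, against 122.9 and 121 for independent lists. Of the 1187 genes changed in both sets, 94.4% moved the same way. The largest shared changes included rises of ANKRD1, HSPA1A, HSPA1B, AMH, DNAH17 and FOSB and falls of G0S2, BASP1, TXNIP, INHBE and HSPA5. BASP1 did not pass in the ALKBH5 set without ALKBH5 scramble replicate 2 (-1.21). The log2 changes of both sets, which have separate scramble libraries, correlated across genes at 0.49 with a covariance of 0.0672. A total of 67 genes changed in opposite directions, 63 of them higher in the ALKBH5 set.

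**Figure D2:**
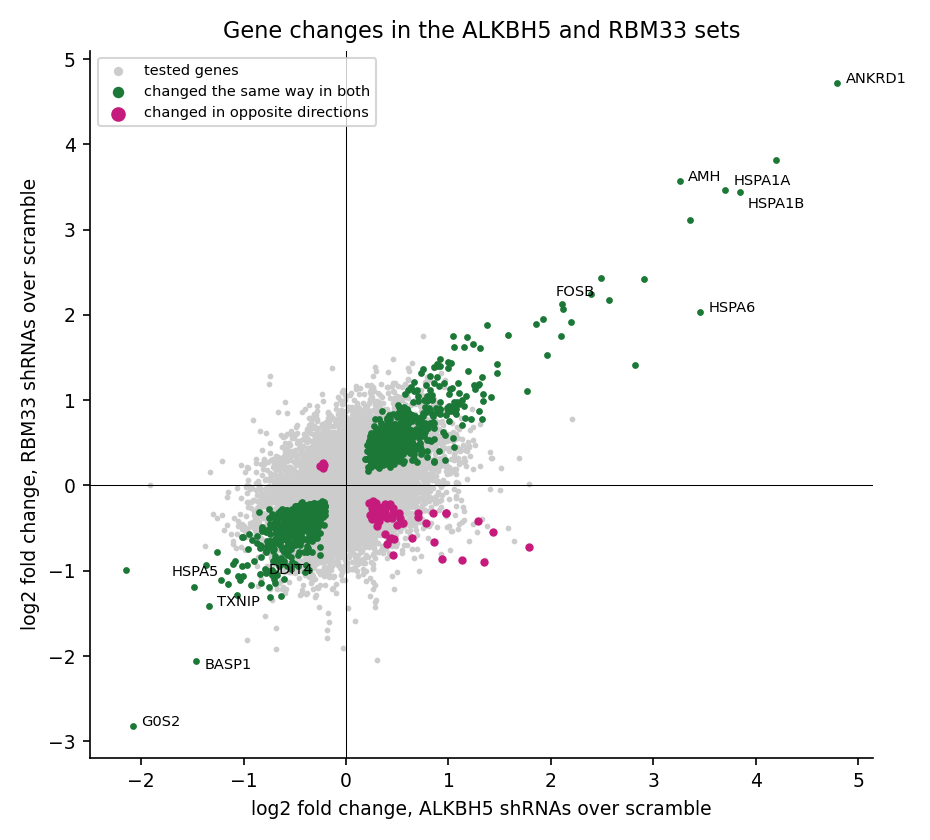
log2 fold change over scramble of each tested gene in the ALKBH5 set (x axis) and the RBM33 set (y axis). Genes changed the same way in both sets (1120, green) lie mostly along the diagonal, with ANKRD1, AMH and the HSP70 genes at the top right and G0S2 at the bottom left, while 67 genes changed in opposite directions (magenta).

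The effects of both targets differed in several gene lists, among them ribosomal protein genes, oxidative phosphorylation and replication histones. In the interaction, 37 of 66 ribosomal protein genes were higher in the ALKBH5 effect than in the RBM33 effect and 0 lower (57 and 0 adjusted over the list alone). The list had a median difference of 0.41, a camera adjusted p of 4.1e-44 and adjusted p = 0.11 with an estimated correlation. Oxidative phosphorylation genes were higher in 11 of 37 cases (17 adjusted over the list alone, median 0.35, camera adjusted p = 6.3e-14, adjusted p = 0.07 with an estimated correlation). Replication histones were higher in 8 of 13 cases (11 adjusted over the list alone, median 0.73, camera adjusted p = 1.5e-18, adjusted p = 0.028 with an estimated correlation). Nuclear noncoding RNA was higher in 5 of 18 cases (8 adjusted over the list alone, median 0.49, camera adjusted p = 1.3e-05, adjusted p = 0.24 with an estimated correlation). Mitochondrially encoded genes were lower in 3 of 13 cases (8 adjusted over the list alone, median -0.36, camera adjusted p = 2.2e-08, adjusted p = 0.32 with an estimated correlation). Without ALKBH5 scramble replicate 1 their median was -0.23, and that of nuclear noncoding RNA was 0.29 without ALKBH5 scramble replicate 2. The ATF4 list was higher on balance (1 higher, 1 lower, 6 and 2 adjusted over the list alone, median 0.15, camera adjusted p = 0.007, adjusted p = 0.07 with an estimated correlation). Splicing factors were lower on balance with 0 single calls (1 higher and 5 lower adjusted over the list alone, median -0.09, camera adjusted p = 0.0097, adjusted p = 0.36 with an estimated correlation), a call that did not pass without RBM33 scramble replicate 2 (median -0.05, 0.057) or with the length trend removed (median -0.01, camera adjusted p = 0.36). With the length trend removed the median of the ATF4 list was 0.08 (camera adjusted p = 0.04) and that of nuclear noncoding RNA 0.30 (2.7e-05). The interaction called 491 genes in limma, 366 higher and 125 lower (74.5% higher), and DESeq2 gave 64.2% higher. The count was 321 without ALKBH5 scramble replicate 1, 306 without ALKBH5 shRNA-2 replicate 1, and 281 and 266 without RBM33 scramble replicates 1 and 2.

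The scramble groups of both sets differed from each other as well, in a comparison that is also part of the interaction. Ribosomal protein, histone, oxidative phosphorylation, noncoding RNA and ATF4 list genes were called in both comparisons. With the length trend removed, hypoxia genes also passed in the interaction (median 0.15, camera adjusted p = 0.02) and mitochondrially encoded genes also passed between the scramble groups (median 0.14, camera adjusted p = 0.0012). Of 66 ribosomal protein genes, 56 were lower in the ALKBH5 scramble libraries than in the RBM33 scramble libraries and 0 higher (64 and 0 adjusted over the list alone). The list had a median of -0.40, a camera adjusted p of 1.4e-69 and adjusted p = 0.062 with an estimated correlation. Replication histones were lower in 12 of 13 cases (12 adjusted over the list alone, median -0.57, camera adjusted p = 7.4e-22, adjusted p = 0.023 with an estimated correlation). Oxidative phosphorylation genes were lower in 10 of 37 (19 adjusted over the list alone, median -0.26, camera adjusted p = 1.2e-18, adjusted p = 0.049 with an estimated correlation). Nuclear noncoding RNA was lower in 6 of 18 cases (7 adjusted over the list alone, median -0.43, camera adjusted p = 7.8e-07, adjusted p = 0.18 with an estimated correlation). ATF4 list genes were lower in 3 of 28 cases and higher in 1 (5 and 1 adjusted over the list alone, camera adjusted p = 0.00086, adjusted p = 0.049 with an estimated correlation), and hypoxia genes lower in 5 of 28 (6 adjusted over the list alone, camera adjusted p = 0.0069, adjusted p = 0.27 with an estimated correlation). Limma called 452 genes between the scramble groups, 49 higher and 403 lower in the ALKBH5 set (10.8% higher, against 21.6% by DESeq2). The count was 248 without ALKBH5 scramble replicate 3, and 241, 265 and 284 without RBM33 scramble replicates 1, 2 and 3. Between the ALKBH5 shRNA and RBM33 shRNA libraries the median of the ribosomal list was 0.01 and limma called 55 genes. Since the sets differ already in their scramble libraries, any difference between the effects of ALKBH5 and RBM33 shRNA is measured across a difference between sets.

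**Figure D3:**
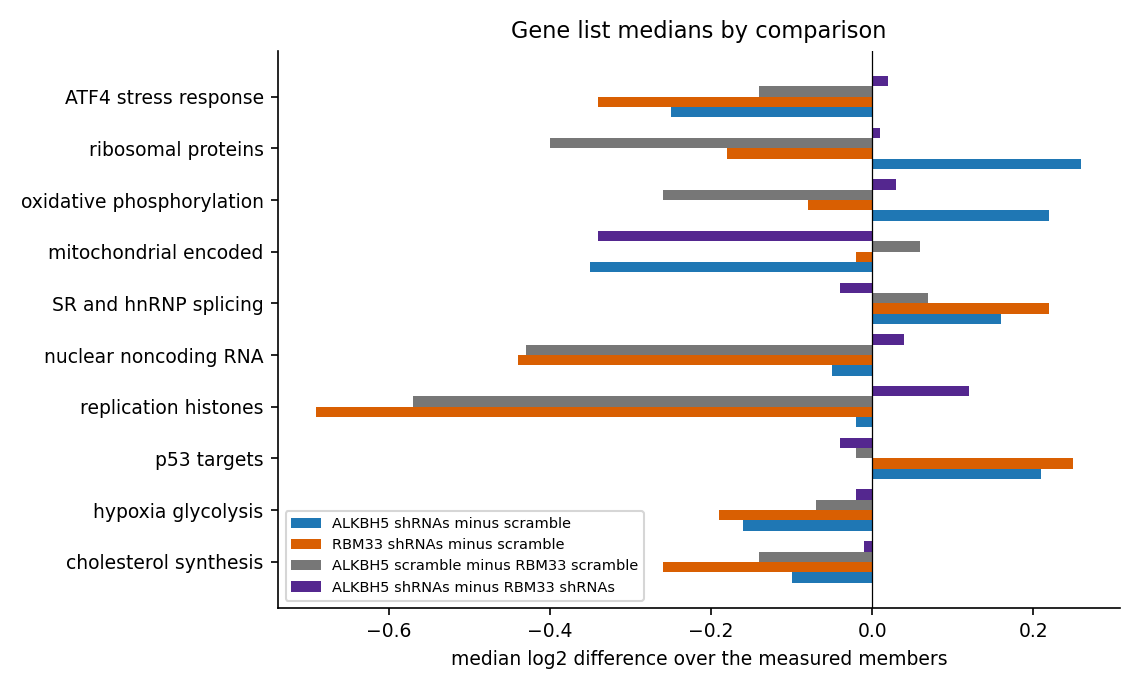
Median log2 difference over the measured members (x axis) of 10 gene lists in 4 comparisons (bars). The ATF4 list was below 0 against scramble in both sets, while the ribosomal protein list was at 0.26 in the ALKBH5 set, -0.18 in the RBM33 set, -0.40 between the scramble groups and 0.01 between the shRNA libraries.

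m6A was higher at most listed peaks in all 4 of the authors' deposited tables of effects. PGK1 had the largest effect in each table at the start of the gene (chromosome X, 78104248 to 78129295), with peaks from 78104169 or 78104219 and effects of 5.99 and 6.37 on the natural log scale for ALKBH5 shRNA-1 and shRNA-2 and of 8.60 and 8.73 for RBM33 shRNA-1 and shRNA-2. These peaks begin outside the RefSeq gene span, and whether their reads come from the PGK1 transcript was not tested. SF3A2, a splicing factor gene, had effects of 1.43, 2.96, 3.76 and 3.82 at chromosome 19, 2248330 to 2248579, or within it. The histone methyltransferase gene KMT2D had effects of 1.77, 2.44 and 1.78 in the first 3 of these tables and a higher peak in the last, near chromosome 12, 49040670 to 49040769, and CAB39 of 1.55, 2.69, 2.45 and 2.61 near chromosome 2, 230713909 to 230714058. MAT2A, which encodes the enzyme that makes the methyl donor S-adenosylmethionine, had effects of 2.11, 4.14, 3.08 and 2.81 at separate positions within its span. CBS also had higher peaks in all 4 tables (1.06, 1.14, 0.96 and 0.91), but has a near-identical copy and is uncertain. DDIT4 had higher m6A at chromosome 10, 72273919 to 72274018, with ALKBH5 shRNA-1 (2.80, p = 6.6e-08 in the authors' deposited table) and at 72275388 to 72275687 with ALKBH5 shRNA-2 (1.20, p = 2.5e-16). In the authors' deposited RBM33 tables its peak at 72275388 to 72275437 had effects of 0.62 and 0.55. Lower peaks were listed as well, 4 in KMT2D against 83 higher over all 4 tables, 1 in DDIT4 against 13 and 1 in PGK1 against 4.

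The ALKBH5 tables list 13120 differential peaks for shRNA-1 (8490 higher, 4630 lower, 64.7% higher) and 19251 for shRNA-2 (13953 higher, 5298 lower, 72.5% higher). The RBM33 tables list 2070 for shRNA-1 (1814 higher, 256 lower, 87.6% higher) and 3268 for shRNA-2 (2860 higher, 408 lower, 87.5% higher). The median effect of higher peaks lay between 1.04 and 1.08, a ratio of between 2.83 and 2.95. The most significant peaks with ALKBH5 shRNA-1 included those in the linker histone gene HIST1H1E (-1.79), MRPL12 (-1.08), MZT2B (-1.66), NUCKS1 (1.70) and nucleolin, NCL (1.29), and with shRNA-2 those in EEF2 (0.97), SPTBN1 (1.93) and YBX1 (0.88). With RBM33 shRNA-1 and shRNA-2 they included ANKRD11 (-1.60 and -1.69), SF3A2, RERE (1.15), FANCA (1.19), INF2 (-1.55) and LARP1 (2.94 with shRNA-2). Peaks overlapping by at least 1 base between the tables of 1 target had the same direction in 97.9% of pairs for ALKBH5 (3859 peaks of shRNA-1) and 100% for RBM33 (647 peaks of shRNA-1). The tables of 1 target share their scramble libraries, and no chance level could be simulated for them. Between the targets, which do not share scramble libraries, between 11.9% and 29.2% of the peaks of the smaller table overlapped, and these had the same direction in between 90.8% and 98.1% of pairs. Between 64.7% and 87.6% of the peaks of a table were higher, so unrelated peaks would also often share a direction, within and between targets. In the 4 tables of m6A fractions the authors list 721, 182, 20 and 18 peaks, of which 472, 128, 6 and 7 overlap the effect tables. The direction was the same in 525 of 536, 149 of 155, 6 of 6 and 9 of 9 pairs.

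**Figure D4:**
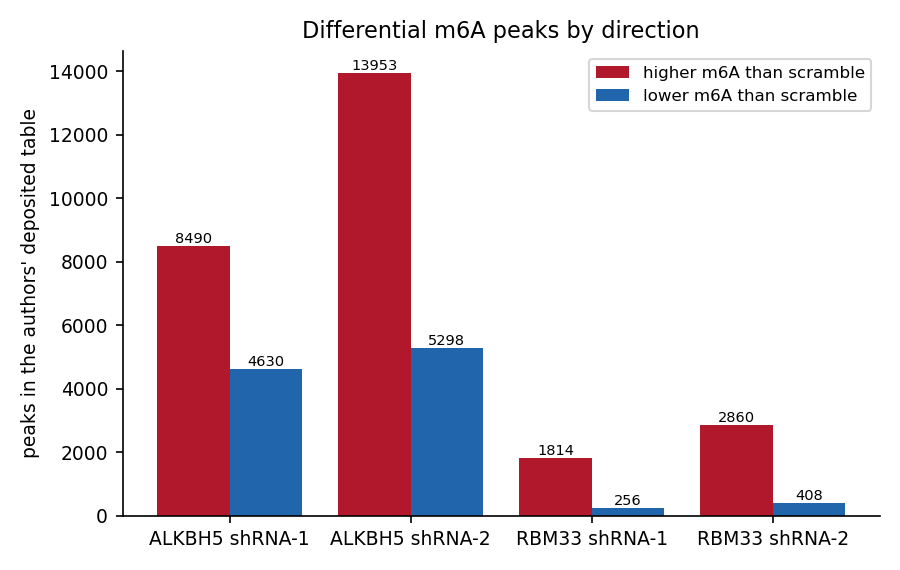
Number of differential m6A peaks with higher (red) and lower (blue) m6A than scramble in each of the authors' deposited tables of effects (y axis, from 0). Higher peaks outnumber lower ones in all 4 tables.

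Genes with higher m6A overlapped between targets. A higher peak in at least 1 ALKBH5 table was found for 6519 of 18166 tested genes and in at least 1 RBM33 table for 2394. Both held for 1926 genes, against 859.1 for independent sets (odds ratio 10.0, and 4.56 within expression deciles). Lower peaks overlapped in 321 genes against 130 (odds ratio 5.69, and 4.26 within deciles, Fisher's exact p = 1.6e-75). Discordant overlaps were also above the values for independent sets. They held 318 genes higher with ALKBH5 and lower with RBM33 against 173.3 (2.61 within deciles). Another 1258 were lower with ALKBH5 and higher with RBM33 against 644.6 (1.92 within deciles), and a gene with several peaks can enter on both sides. The background was all tested genes, with or without a peak that could be tested. How much of each excess comes from this background could not be told. A total of 454 genes had a higher peak in all 4 tables and 24 a lower one. Of the gene lists, which were not tested for enrichment, SR and hnRNP splicing factors had a higher peak in 31 of 33 cases with ALKBH5 and 18 with RBM33, the m6A machinery in 23 and 7 of 27, cell cycle genes in 32 and 11 of 38, and mRNA export genes in 17 and 5 of 21. Shares were lower for ribosomal proteins (29 and 7 of 66), mesenchymal genes (6 and 1 of 17), interferon genes (4 and 0 of 17) and mitochondrially encoded genes (0 and 0 of 13). ATF4 list genes had a higher peak in 20 and 15 of 28 cases. Among them was ATF4 itself near chromosome 22, 39521609 to 39522059, with effects of 1.27, 1.5, 0.83 and 0.82, and with 1 lower against 10 higher peaks in all.

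RNA levels of genes with higher m6A differed little from expression-matched random sets. The median log2 RNA change of such genes was below that of the matched sets by a difference of -0.010 for ALKBH5 shRNA-1 (permutation p = 0.012, adjusted 0.019) and -0.008 for ALKBH5 shRNA-2 (permutation p = 0.037, adjusted 0.049). For RBM33 shRNA-1 and shRNA-2 the differences were -0.012 (permutation p = 0.21) and -0.008 (permutation p = 0.23), which did not pass. With stricter peaks the difference for ALKBH5 shRNA-1 was -0.004 and did not pass, and that for ALKBH5 shRNA-2 was -0.010 (permutation p = 0.038, unadjusted). Those for RBM33 were 0.010 (permutation p = 0.40) and 0.021 (permutation p = 0.03, unadjusted, in the opposite direction). Genes with lower m6A had higher RNA than matched sets, by 0.069 and 0.022 for the ALKBH5 shRNAs and by 0.177 and 0.142 for the RBM33 shRNAs (permutation adjusted p between 0.00027 and 0.0006, where an unadjusted 0.0001 is the smallest the random sets can give). The m6A effects and the RNA changes share the same input groups, so errors in the input enter both, and genes are not independent replicates.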

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

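The direct comparison of the shRNA libraries, the removal of the length trend and the tests of explanations that use them were chosen only after the results were seen, while the interaction and the gene lists were planned.

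The effects of both sets differed for 33 of 167 named genes, 27 higher and 6 lower in the ALKBH5 effect than in the RBM33 effect (limma adjusted p up to 0.046). Ribosomal protein genes were higher, with RPL27 at 0.86, RPL35 at 0.81, RPS27 at 0.77, RPLP1 at 0.73, RPL12 at 0.58, RPL32 at 0.56, RPS21 at 0.53 and RPL10 at 0.42. Replication histones were higher too, with H2AC11 at 1.27, H3C10 at 1.08, H2AC17 at 1.06, H3C2 at 1.03, H4C3 at 0.79 and H2AC13 at 0.77. So were the respiratory chain genes COX6A1 (1.20), UQCRQ (0.99), UQCRC1 (0.78) and COX6C (0.67) and the small RNAs RN7SK (1.30), TERC (0.89), RN7SL1 (0.81) and RN7SL2 (0.73). Among the rest, the melanosome gene PMEL (2.23), the stress gene GADD45B (1.17), the ubiquitin-conjugating enzyme UBE2C (0.75), PGK1 (0.59) and SQSTM1 (0.51) were higher. MT-ATP8 (-0.83), MT-ND4 (-0.58), MT-ND5 (-0.54), the kinesin gene CENPE (-0.56), ALKBH5 (-0.47) and ZC3H13 (-0.43) were lower.

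Of the gene lists, replication histones (median 0.73), nuclear noncoding RNA (0.49), ribosomal proteins (0.41), oxidative phosphorylation (0.35) and the ATF4 stress response (0.15) were higher in the ALKBH5 effect, and mitochondrially encoded genes (-0.36) and splicing factors (-0.09) lower. With an estimated correlation only replication histones passed in camera (adjusted p = 0.028), against 0.24, 0.11, 0.07 and 0.07 for the other higher lists and 0.32 and 0.36 for the lower ones. The splicing factor median was -0.01 with the length trend removed.

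A difference between the scramble groups may account for the ribosomal protein and replication histone genes. Between the ALKBH5 shRNA and RBM33 shRNA libraries the ribosomal list had a median of 0.01 and the histone list of 0.12, so the difference lies mostly on the scramble side, which fits this explanation. With a gene length trend removed from each library, the medians were still 0.36 and 0.62, so the removed part is not the whole cause. The removal was incomplete. Over protein-coding genes, the Spearman correlation of the interaction with gene length was -0.36 before it and -0.08 after it. A remaining part of the length trend therefore stays open as a cause. Oxidative phosphorylation, nuclear noncoding RNA and ATF4 list genes had medians of 0.03, 0.04 and 0.02 between the shRNA libraries. Between the scramble groups their medians were -0.26, -0.43 and -0.14, so these differences also lie mostly on the scramble side. Mitochondrially encoded genes behaved differently, with a median of -0.34 between the shRNA libraries and -0.53 in the interaction with the length trend removed. These values argue against either explanation as the whole cause for them. A part on the scramble side stays open. With the length trend removed the scramble groups differed by a median of 0.14, and without ALKBH5 scramble replicate 1 the interaction median was -0.23.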

How the results depend on the processing

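Tests with the length trend removed, the direct comparison of shRNA libraries and the left-out libraries for gene lists were chosen only after the results were seen.

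ALKBH5, DDIT4, ANKRD1, HSPA1A and HSPA1B kept their calls under every alternative, and of 213 called named results 161 were kept under every alternative run for them (between 15 and 17 each, with only the libraries of a result's own set left out), 52 were lost under at least 1 and 0 reversed. With a replicate block the ALKBH5 count was 2448 and the RBM33 count 2975, and 203 of the 213 results were kept. Replicate numbers did not pair across groups (residual correlations between -0.08 and 0.07). Leaving out each library gave counts from 1710 to 2358 for ALKBH5, 2062 to 3112 for RBM33, 541 to 1229 for ALKBH5 shRNA-1, 592 to 1400 for ALKBH5 shRNA-2, 953 to 1541 for RBM33 shRNA-1, 266 to 579 for the interaction and 241 to 330 for the scramble groups, and the cause was not tested. The interaction count was 323 with the length trend removed. Over 13783 protein-coding genes the interaction had a Spearman correlation of -0.36 with gene length, and the scramble comparison one of 0.36. With the trend removed these were -0.08 and 0.1. What caused the length trend was not tested. The count was 55 between the shRNA libraries directly, which drops the scramble libraries by construction. ALKBH5 shRNA-2 against shRNA-1 gave 1 gene by DESeq2 and 0 in limma, and the cause was not tested. Of 66 called list results 12 were kept with an estimated correlation. The correlation setting was all that changed between these camera runs, so the calls that were lost rest on the preset value of 0.01. Stricter m6A peaks left 6611, 9580, 1102 and 1727 peaks, fewer by construction. With them the RNA difference of genes with higher m6A was -0.004 for ALKBH5 shRNA-1 and reversed to 0.01 and 0.021 for RBM33 shRNA-1 and shRNA-2, and the cause was not tested. ATF4 in the RBM33 set, not called, ranged from -0.01 to 0.05 over left-out libraries. In the ALKBH5 set ATF4 was called higher (0.21, limma adjusted p = 0.026), against the direction of its list, and lost this call under 5 of 16 alternatives. Its RNA values were also chosen after they were seen.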

Other observations

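The choice of the heat shock genes, the tests of explanations for the heat shock and squamous genes and the tests by splits of libraries were written only after the results were seen.

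Heat shock genes rose in both sets beyond the HSP70 copies. Of 18 measured heat shock genes other than HSPA1A and HSPA1B, HSPA6 included, 14 rose in the ALKBH5 shRNA libraries, 14 in the libraries labelled RBM33 shRNA and 13 in both. The constitutive chaperone HSPA8 rose by 1.33 and 0.99 in the ALKBH5 and RBM33 sets, the HSP110 gene HSPH1 by 1.01 and 1.07, the co-chaperones DNAJA1 by 0.82 and 0.88 and DNAJB1 by 0.60 and 0.89, HSP90AA1 by 0.62 and 0.85, the mitochondrial chaperonin HSPE1 by 0.74 and 0.67, and BAG3 by 0.41 and 0.57. HSPA4 (-0.06 in both sets) and DNAJB4 (0.14 and 0.12) were not called, and HSPA4L fell in the ALKBH5 set (-0.24, limma adjusted p = 0.049).

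Reads shared between HSPA1A and HSPA1B cannot be the whole cause of the heat shock rise, since 13 other genes rose in both sets as well, among them HSPH1 and DNAJA1. Apart from HSPA6, these genes were chosen after their values were seen. The rise could also come from both targets being lowered. The lower bound of the RBM33 change is -0.23 against an ALKBH5 change of -0.53, which excludes an equal fall of both transcripts only. Protein levels were not among the data used, so whether lowering of the targets caused the rise could not be decided. A difference in handling between scramble and shRNA dishes is named by no label and was not tested, since it would follow the groups.

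Keratinocyte differentiation genes and squamous keratins were mostly low in a line labelled squamous carcinoma, while more of the basal squamous genes were measured. Of 29 basal squamous genes 19 reached a mean of 1 CPM, 14 reached 5 CPM and 3 reached 50 CPM, with DST highest at 271 CPM. Of 36 keratinocyte genes 7 reached a mean of 1 CPM, and of 18 epithelial genes 5 reached 5 CPM, with DSP highest at 192 CPM. Of 14 neural or melanocyte genes 3 reached 5 CPM, and only the neurofilament gene NEFL, at 182 CPM, reached 50 CPM. In the authors' deposited ALKBH5 shRNA-1 DESeq2 table, KRT5 had a mean of 3.67, KRT14 of 2.48 and TP63 of 6.44 normalized counts, against 2330 for IGF2BP1, 1320 for NEFM and 645 for LIN28B. IGF2BP1, NEFM and LIN28B were chosen after their levels were seen, so they do not represent a cell type list. Depth is excluded as the cause, since 3 reads were worth at most 0.66 CPM, and a filter in the CPM table is excluded for KRT5, KRT14, KRT17, KRT6A and TP63, since the highest of these 5 genes was TP63 at 6.44, under the table's median of 23.4. Whether the culture was the labelled line was not tested, as no reference profile of the line was used here, and no biological explanation was tested.

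Random assignment of libraries to groups was tested by splitting them in every other way or in 100 ways. Except for RBM33 shRNA-2 and the scramble groups, both shRNAs of a set were pooled into 1 group for these splits, so the real counts differ slightly from those of the fit with 6 groups. Only the real split reached the real value for the ALKBH5 count (2758 genes, highest other split 694) and the RBM33 count (3301, highest other 168). The same held for the genes changed the same way in both (1136, highest other 0) and the interaction (510, highest other 309). The shares of splits were 0.0286, 0.0179, 0.01 and 0.01, the smallest possible here. They argue against random assignment of these libraries only. As replicates may be technical, a difference between cultures unrelated to the shRNAs is not excluded. For RBM33 shRNA-2 (2499, highest other 2) and the scramble groups (452, highest other 0) the 10 splits are too few.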
